A study of Mus musculus with 4 samples.

How the data were processed

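Total RNA from cultured mouse resident peritoneal macrophages was measured on 1-colour Cy3 Agilent arrays, with 1 array for each of 4 groups. The groups were wild type without LPS, wild type with LPS, CD163-deficient without LPS and CD163-deficient with LPS. Per the file headers, the scanner files hold spot intensity from Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. The deposited processed signal of each spot is an intensity with local background and spatial trends removed inside the array, and it was not adjusted between arrays. A value table was deposited too. Each of its columns had a median of 175.3, its values were on a linear scale, and they differed from a quantile normalization of the processed signals by a median of 0.0012 on the log2 scale or less. That table was used as an alternative and not as the main source.

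The processed signal was taken as log2, and the 75th percentile of the non-control probes of the same array was subtracted, so that a level of 0 stands for that percentile. Spots of 1 probe were averaged, which gave 39429 probes from 43020 spots. Probe names came from the RefSeq accession in the array annotation for 26854 probes, from a current symbol for 3752 and from an older symbol for 625. The other 8198 probes kept the name in the file. Together they named 30156 genes and transcripts, 7238 of them with more than 1 probe, and the probe with the highest mean level over the 4 arrays stood for the gene. Chromosome positions are those of the array annotation, on the mouse assembly mm9. A RefSeq annotation of a later assembly served for names alone.

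A probe counted as detected where at least 50% of its spots were well above background by the flag of Feature Extraction. A gene entered a comparison when it was detected on at least 1 of the arrays compared, and the comparison of LPS responses needed detection on all 4 arrays (23904 genes). Where a gene was detected on 1 array of a pair, its difference was bounded with the other array set to the higher of the probe's own level there and the lowest level among the probes well above background on that array, and it is given as "at least" a fold.

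Differences are log2 values of 1 array minus another. With 1 array per group the pairwise comparisons and the LPS response difference have no residual degrees of freedom, so no p-value, interval between cultures or paired analysis is given for them. A fit of additive genotype and LPS effects would leave 1 degree of freedom, if the LPS response were taken as equal in both genotypes, and it was left out. Genes were counted by size alone, at 2-fold or more. Each of 32 gene lists (10 of cell type markers, 19 of pathways or functions and 3 controls) was described by the median difference of its compared members, taken as measured. That median was placed among 10000 random lists of the same size, matched on mean level in 20 bins (seed 1). A list is said to stand apart at or above percentile 97.5 or at or below percentile 2.5. By chance 0.8 of the 32 lists would do so on each side of each comparison, but genes of 1 list vary together, which random lists do not copy. Lists share members, so they are not independent. Of 28 alternative activation genes 16 are in another list, as are 10 of 30 markers of large peritoneal macrophages, 8 of 30 complement and efferocytosis genes and 6 of 34 matrix and protease genes. Across genes, Pearson and Spearman correlations describe how alike pairs of differences were, and genes are not independent replicates.

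The lists, the 2-fold rule, the comparisons and the rule for named genes were fixed before the data were examined. The rule names Cd163, the 10 genes with the largest measured difference in each direction of each pairwise comparison, the 5 with the largest bound, the 8 with the largest difference between LPS responses, and up to 5 members of each list. Genes with clone or predicted names were passed over, as were genes whose probes detected on the arrays compared differed in sign. A further group, genes at a level of -2 or more, was chosen after the values were seen, because most genotype differences lay in dim probes. For a gene compared between genotypes or LPS states it needs that level on every array compared.

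The alternatives were normexp background correction (limma 3.58.1, offset 50), quantile normalization, scaling to the median of detected probes, the deposited value table, the mean of all probes of a gene, detection required on both arrays, no detection filter, and the level of at least -2 added later. Detection on both arrays was not a separate setting for the LPS response difference, which already asked for all 4. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

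The steps that take differences, count genes and place lists were tested on simulated gene levels with the noise of the spots. Levels, floor and noise came from the wild-type array without LPS each time, so the 4 comparisons were random draws of 1 setting. Scaling, averaging of spots, choice of probe and the background flag were not tested. Genes given a log2 change of 1.5 were called in the right direction at rates of 90.0% to 97.0% over the 4 draws, and those given 2.5 at rates of 93.0% to 95.0%. Unchanged genes were called 2-fold at rates of 0.740% to 0.834%, with 0 of those at a level of -2 or more. Of 100 unchanged lists 0 to 3 stood apart in each draw, and 50 of 50 lists shifted by 0.2 did so. Simulated noise holds no difference between cultures. It took the median spread of spots at each level, so probes with a wider spread were not copied.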

Results

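Transcript levels were measured in resident peritoneal macrophages, which live in the fluid of the abdominal cavity, from wild-type and CD163-deficient mice. CD163 is a macrophage surface receptor that takes up haemoglobin bound to haptoglobin. The cells were kept in medium with serum for 2 days, and part of them received lipopolysaccharide (LPS), an endotoxin of Gram-negative bacteria, at 100 ng/mL for 1 day. Each of the 4 groups holds 1 array, so every difference is between single arrays and has no replicate check. The 75th percentile of the processed intensity was 909.6 for wild type without LPS, 1325 for wild type with LPS, 1258 for CD163-deficient without LPS and 1188 for CD163-deficient with LPS. In the same order, 24685, 26498, 25672 and 24902 of 30156 genes were well above background, and no spot was saturated. Probes with 10 spots had a median standard deviation of 0.10, 0.11, 0.10 and 0.09 (log2) between spots, and a 90th percentile of 0.51, 0.43, 0.40 and 0.39. These values cover spread within an array and not between cultures. Differences are given as log2 values unless a fold is named, and "higher" and "lower" describe the arrays at hand.

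Cd163 itself was near the floor on every array. Its 1 probe, on chromosome 6 from 124270436 to 124270495 (mm9), had a level of -5.47 in wild type without LPS, -5.01 in wild type with LPS, -6.0 in CD163-deficient cells without LPS and -5.48 in CD163-deficient cells with LPS. It was well above background on all 4 arrays. Among detected genes it lay at percentile 0.895 in wild type without LPS and at percentile 10.0 in wild type with LPS. The CD163-deficient level was lower by a log2 difference of -0.53 without LPS and -0.47 with LPS. Of 1130 genes with a similar level, 21.6% differed at least as much without LPS, and of 1335 genes 22.6% did so with LPS. The files do not say which part of the gene was deleted, and a probe outside that part would check nothing about the genotype.

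**Figure D1:**
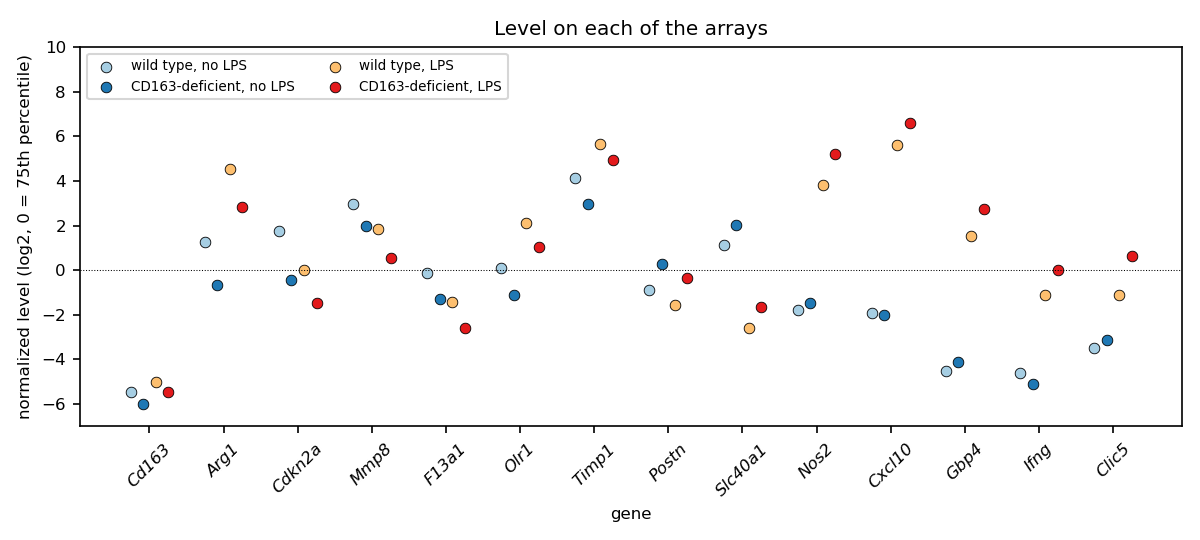
Normalized level (log2, 0 is the 75th percentile of the array) of 14 genes, with 1 point per array coloured by group. Cd163 lies between -6.0 and -5.01 on the 4 arrays, Arg1 is lower in CD163-deficient cells in both states, and Nos2 is highest in CD163-deficient cells with LPS (5.21).

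The response of wild-type cells to LPS was led by inflammatory mediators. Lcn2, which encodes the iron-sequestering protein lipocalin 2, was 209-fold higher with LPS (7.70), and Cxcl10, a chemokine for T cells, was 189-fold higher (7.56). The cytokine genes Il1a (7.43), Il12b (7.23) and Il1b (6.32) followed, with the interferon-induced genes Ifi44 (6.31), Ifit1 (6.07) and Gbp4 (6.05), the neutrophil chemokine gene Cxcl2 (6.05) and the signalling gene Rasgrp1 (6.17, and 3.63 on its other probe). Cxcl3 was not well above background without LPS and was at least 1247-fold higher with it, and the same held for Gp6 (at least 73.6-fold), Saa2 (58.6-fold) and Trem3 (41.3-fold). Lower with LPS were Rasgrp3 (-5.16), the lysosomal transporter gene Slc46a3 (-4.72), Mamdc2 (-4.26), Sox7 (-3.99), Hpgd, which degrades prostaglandins (-3.97), Cd34 (-3.74, and -0.73 on its dimmer probe), the iron exporter gene Slc40a1 (-3.71), the lectin gene Clec10a (-3.70) and Gas6, a bridge to dying cells (-3.67).

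By group, 55 of 56 interferon-stimulated genes were higher with LPS in wild type, 54 of them at least 2-fold, with a median of 3.23. All 26 compared cytokine genes were higher (median 1.32, and 0.86 with normexp background correction), as were 20 of 27 chemokine genes (1.77) and all 21 genes of class I antigen presentation (1.63), with H2-Q8 at 3.45 and Tap1 at 2.66. The list of nitric oxide, prostaglandin and antimicrobial genes had a median of 2.04, with Nos2, the inducible nitric oxide synthase, at 5.60 and Acod1, which makes itaconate, at 4.51. NF-kB feedback genes had a median of 1.38, with Socs3 at 4.52 and Socs1 at 4.42. Each of these 6 lists lay at percentile 100 of its random lists. So did the unfolded protein and integrated stress list (1.03, 29 of 32 higher, with Mthfd2 at 2.82 and Trib3 at 2.20) and the glycolysis and hypoxia list (0.41, 25 of 35 higher, with Pfkfb3 at 2.11). The lists of matrix and protease genes (0.34, percentile 99.98) and of scavenger and pattern receptors (0.21, percentile 99.79) also stood apart upward while holding members in both directions, as with Clec4e at 3.97 and the mannose receptor gene Mrc1 at -3.37.

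Cholesterol synthesis genes were lower with LPS in wild type, 22 of 25 of them (median -1.01, percentile 0), with Insig1 at -2.95 and Idi1 at -2.68. Of 54 cell cycle genes 46 were lower (median -0.55, percentile 0), with Stmn1 at -1.72. Mesothelial and fibroblast markers were lower in 21 of 24 cases (median -0.63, percentile 0), with Upk1b at -2.60 and Krt18 at -2.01. In total 1708 genes were at least 2-fold higher and 1343 at least 2-fold lower of 26676 compared, and 512 and 264 were at least 4-fold apart. With normexp the 2-fold higher count was 1053 and the 4-fold lower count 106, and at a level of -2 or more the 4-fold counts were 309 and 102. The LPS difference of upstream probes exceeded that of downstream probes by a median of 0.13 over 2628 transcripts in wild type (95% bootstrap interval 0.101 to 0.152), a measure that RNA integrity can move, and by 0.039 in CD163-deficient cells.

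CD163-deficient cells with LPS, set against those without it, showed most of the same picture. Cxcl10 was 395-fold higher (8.63), and Lcn2 (7.96), Il12b (7.59), Il1a (7.04), Gbp4 (6.89), Nos2 (6.69), Il1b (6.67), Ifi44 (6.57), Il6 (6.42) and Cstdc5 (6.36) completed the 10 largest measured differences among named genes. Cxcl3 was at least 1082-fold higher. Mamdc2 (-5.21), Slc46a3 (-4.96), Hpgd (-4.80), Rasgrp3 (-4.69), the chemokine receptor gene Cxcr4 (-4.31) and the Wnt regulator gene Dkk2 (-4.01) were lower. Interferon-stimulated genes had a median of 3.30, with 55 of 56 higher, the chemokine list 2.03, the nitric oxide, prostaglandin and antimicrobial list 2.31, class I genes 1.93, cytokine genes 1.45 (1.21 with undetected members at their bound) and NF-kB feedback genes 1.44, all at percentile 100. Cholesterol synthesis genes had a median of -1.5, with 24 of 25 lower and Idi1 at -2.59. Cell cycle genes had a median of -0.66, with 50 of 55 lower. Alternative activation genes stood apart downward (median -0.28, percentile 0.310), with Mrc1 at -3.89 and Pparg, a nuclear receptor gene of lipid metabolism, at -3.03, while Arg1 was higher (3.48). That call ended with normexp (percentile 5.34). In total 1892 genes were at least 2-fold higher and 1439 at least 2-fold lower of 26146, and with normexp the lower count was 865.

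The LPS differences of both genotypes ran along 1 line across genes. Over 23904 genes Pearson's r was 0.831 and Spearman's rho 0.656, with a slope of 0.878. Of the genes at least 2-fold higher with LPS, 1135 were shared (1671 in wild type and 1809 in CD163-deficient cells of 25822 genes), where independent sets would share 117.1. Of those lower, 873 were shared (1264 and 1409), where independent sets would share 69.0.

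**Figure D2:**
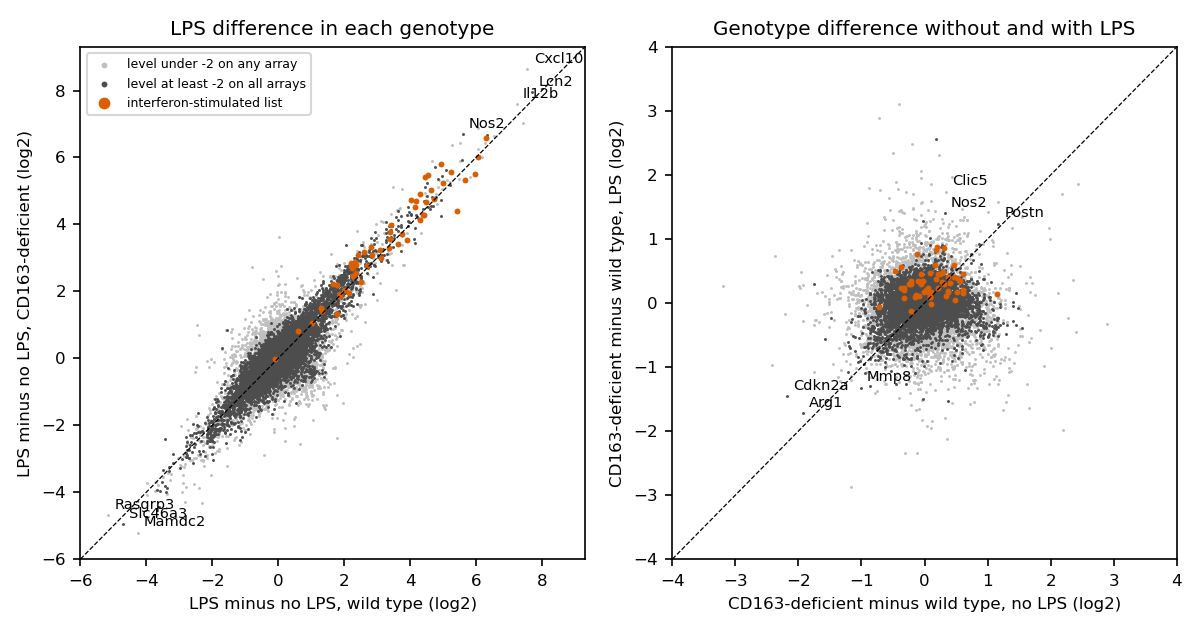
Each point is a gene well above background on all 4 arrays, with differences in log2. On the left the LPS difference in CD163-deficient cells is plotted against that in wild type (r 0.831), and on the right the genotype difference with LPS against that without LPS (r 0.0252). Dark points have a level of at least -2 on all arrays, orange points are interferon-stimulated genes, and the dashed line marks equal values.

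The comparison of genotypes without LPS asks how resting cells labelled CD163-deficient differ from wild type. Arg1, the arginase that competes with nitric oxide synthase for arginine, was lower in CD163-deficient cells (-1.93), with levels of -0.65 against 1.27 in wild type (chromosome 10, 24636194 to 24636253). Cdkn2a, which encodes inhibitors of cell division, was lower as well (-2.18, chromosome 4, 88920405 to 88920464). The other genes with the largest measured differences had levels under -2 on the array where they were lower. They included Clec5a (2.40), Ceacam12 (2.35, and 0.24 on its other detected probe), Zfp354b (2.28), Krt17 (1.97), Spin2c (1.96), Dgkg (1.89) and Ctnna2 (1.83) on the higher side, and Dytn (-3.19), Spink12 (-2.62), Wbp2nl (-2.37), Rtl1 (-2.17) and Fscn2 (-1.82) on the lower side. Trim15 (at least 9.29-fold) and Fgf21 (at least 5.32-fold) were detected in CD163-deficient cells and were not well above background in wild type. Ncr1 (at least 11.6-fold) and Cldn18 (at least 10.8-fold) showed the reverse. Fgf21, Ncr1 and Cldn18 were each well above background on just 1 of the 4 arrays. Dytn, Spink12, Wbp2nl, Rtl1 and Fscn2 each had their highest level on the wild-type array without LPS.

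Among brighter genes, a group chosen after the values were seen, Htatsf1 (1.55), Hpgds, the prostaglandin D synthase of blood cells (1.45), Rassf3 (1.41), Dkk2 (1.34), Postn, which encodes the matrix protein periostin (1.17), and Slfn4 (1.15) were higher in CD163-deficient cells without LPS. Srebf2, a regulator of cholesterol synthesis, was higher by 1.49 on its brighter probe and by 0.40 on its other probe, and Rock1 by 1.17 and 0.20. Htatsf1, Srebf2 and Rock1 each had their lowest level on the wild-type array without LPS and their highest on the CD163-deficient array without LPS. With LPS their genotype differences were -0.39, -0.08 and -0.24. A fault of 1 array without LPS cannot be told apart here from a difference that is absent with LPS. Lower were Serpinb1a (-1.58), the oxidized lipoprotein receptor gene Olr1 (-1.21), Plac8 (-1.20, and -0.68 on its other probe) and the protease inhibitor gene Timp1 (-1.18).

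Without LPS, matrix and protease genes were the list furthest down in CD163-deficient cells, with 27 of 33 lower and a median of -0.41 (percentile 0). Timp1, the clotting factor XIII gene F13a1 (-1.17), the collagenase gene Mmp8 (-1.01) and Has2 (-0.93) led it, and beside it 4 of 6 abundant stromal markers were lower (median -0.29), while the mesothelial and fibroblast list as a whole did not stand apart (-0.14, percentile 17.61). Abundant here means a level of 0 or more on both wild-type arrays. Cell cycle genes were lower in 40 of 54 cases (median -0.20, percentile 0). Class I genes (median 0.13, 14 of 21 higher, up to 0.29 over the settings), interferon-stimulated genes (0.09, 34 of 56 higher, up to 0.15) and NF-kB feedback genes (0.08, 19 of 32 higher, with Birc3 at 1.00) stood apart upward. Class II genes (0.09, with Cd74 at 0.51), the LXR, PPAR and lipid list (0.04) and the nitric oxide, prostaglandin and antimicrobial list (-0.01) also stood apart upward, and the signs of these 3 medians turned with normexp, to -0.02, -0.02 and 0.01. All compared genes had a median of -0.06 here, so a list near 0 can lie high among matched random lists. With quantile normalization the calls of NF-kB feedback genes (percentile 97.04), class II genes (percentile 94.97) and the nitric oxide, prostaglandin and antimicrobial list (percentile 91.47) ended, and with normexp those of class II genes (percentile 97.11) and of the LXR, PPAR and lipid list (percentile 96.24) did.

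In total 327 genes were at least 2-fold higher and 299 at least 2-fold lower in CD163-deficient cells without LPS, of 25919. Of these 626 genes 11.3% had a level of -2 or more on both arrays, against 50.1% of the genes compared, which left 46 higher and 25 lower of 12982. With normexp the counts were 48 and 106, so that 31.2% of these genes were higher, against 52.2%.

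The comparison of genotypes with LPS asks how activated cells labelled CD163-deficient differ from wild type. Nos2 was 2.65-fold higher in CD163-deficient cells (1.41, chromosome 11, 78773567 to 78773626), and Arg1 was again lower (-1.72). Apart from Arg1, the 10 largest measured differences of named genes on each side were of genes with a level under -2 in wild type or in CD163-deficient cells. They included Klhl34 (3.51), Gsg1l (3.11), Fhl4 (2.34), Spata24 (2.34), the peroxisomal transporter gene Abcd2 (2.31), Cacna1e (2.23), Kctd8 (2.04) and Prss34 (1.78) on the higher side, and Fam83d (-2.88), Ect2l (-2.34), Plscr4 (-2.13) and Nags (-1.95) on the lower side. Wnk4 (at least 11.5-fold) and Ceacam9 (at least 9.33-fold) were not well above background in wild type, and Klk1b1 (at least 8.20-fold lower) was not so in CD163-deficient cells. Among brighter genes, again chosen after the values were seen, Clic5 (1.74), Serpina3g (1.28), Postn (1.24), Gbp4 (1.23), Ifng, which encodes interferon gamma (1.14), and Il4i1 (1.01) were higher. Sptlc1, of sphingolipid synthesis (-1.53), Iqsec2 (-1.5), Cdkn2a (-1.45), Mmp8 (-1.32), the lectin receptor gene Clec1b (-1.30, and -0.57 and -1.5 on its other probes), Cd24a (-1.27), the thrombomodulin gene Thbd (-1.13), Cd5l (-1.10) and the beta-glucan receptor gene Clec7a (-1.09) were lower.

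Several lists that were higher with LPS were higher again in CD163-deficient than in wild-type cells with LPS. Interferon-stimulated genes were higher in 53 of 56 cases (median 0.29), with Gbp5 at 0.87, Igtp at 0.86, Isg20 at 0.83 and Mx1 at 0.76. All 21 class I genes were higher (0.29, and 0.18 with quantile normalization, with Tap1 at 0.58), as were 25 of 29 genes of the nitric oxide, prostaglandin and antimicrobial list (0.23, down to 0.15 over the settings) and 29 of 32 NF-kB feedback genes (0.20, with Dusp2 at 0.94 and Icam1 at 0.69), all at percentile 100. Class II genes did not stand apart for LPS in either genotype (-0.17 in wild type and -0.02 in CD163-deficient cells). Between genotypes with LPS they were higher (0.19, 11 of 15 higher, percentile 99.93), with Cd40 at 0.91 and H2-Aa at 0.81. The Nrf2 antioxidant list, which did not stand apart for LPS either, was also higher (0.12, percentile 98.72), a call that ended with quantile normalization (percentile 95.61). Cytokine genes went both ways, 13 higher and 13 lower, with Tnf at 0.86, Il15 at 0.76 and Il33 at -1.10. Their median of -0.03 turned to 0.09 with normexp and to 0.01 with undetected members at their bound. Chemokine genes stood apart downward (median -0.18, 17 of 27 lower, percentile 0), with Ppbp at -1.03, Pf4 at -0.84 and Ccl17 at -0.77, although Cxcl9 and Cxcl10 were higher by 0.97 each. Without LPS the chemokine median was also -0.18 (20 of 26 lower), at percentile 13.9, where all compared genes had a median of -0.06.

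Alternative activation genes were lower in CD163-deficient cells with LPS, 20 of 25 of them (median -0.35, percentile 0, up to -0.20 over the settings), a list with 16 of its 28 genes in other lists as well, with F13a1 at -1.20, Socs2 at -1.13 and Mrc1 at -0.86 beside Arg1 and Clec7a. Matrix and protease genes were lower in 27 of 34 cases (-0.47, percentile 0), with Timp3 at -0.91 and the cathepsin K gene Ctsk at -0.86, and beside them the mesothelial and fibroblast markers (-0.21, 17 of 24 lower, percentile 0), with Col3a1 at -0.72 and Col1a1 at -0.70. Cell cycle genes (-0.27, 51 of 55 lower, with Nuf2 at -1.67), markers of large peritoneal macrophages (-0.16, 20 of 30 lower, with Gata6, the transcription factor of that cell type, at -0.67) and the LXR, PPAR and lipid list (-0.19, 21 of 30 lower, with Scd2 at -0.86) were at percentile 0 too. Without LPS the medians of large macrophage markers (-0.16, 19 of 29 lower, percentile 19) and of alternative activation genes (-0.16, 18 of 26 lower, percentile 16.51) were negative as well. Complement and efferocytosis genes had a median of -0.05 (percentile 0.155), which turned to 0.08 with the mean of all probes. Eosinophil markers, all but 1 of 8 higher, had a median of 0.22 (percentile 99.16), a call that ended with normexp (percentile 97.1).

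With LPS 307 genes were at least 2-fold higher and 290 at least 2-fold lower of 26665, and of these 597 genes 4.02% had a level of -2 or more on both arrays, which left 9 and 15. The share that was higher was 51.4%, and it was 73.9% with normexp (96 and 34 genes), 61.4% with quantile normalization and 61.3% with the deposited table.

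Haem and iron genes, the list closest to the known role of CD163, did not stand apart between genotypes. Their median was -0.04 without LPS (13 of 29 higher, percentile 85.45), which turned to 0.05 with quantile normalization, and it was 0.00 with LPS (14 of 28 higher, percentile 12.34). Slc40a1, the iron exporter gene, was higher in CD163-deficient cells in both states (0.92 and 0.93), and Tfrc, the transferrin receptor gene, was lower in both (-0.85 and -0.43). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, was higher in CD163-deficient cells with LPS by 0.43.

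Few genes differed between genotypes in both states. Across 23904 genes the correlation of the genotype differences without and with LPS was 0.0252 (rho 0.0394), and it was -0.0159 with normexp. Of the genes at least 2-fold higher 17 were shared (297 and 187 of 25584), against 2.17 for independent sets, and of those lower 20 were shared (234 and 246), against 2.25. The shared lower genes included Arg1, Cdkn2a, Mmp8, Olr1, F13a1, She and Fam83d, and the shared higher genes included Postn, Krt17 and Kctd8. Opposite directions were found too, with 36 genes higher without LPS and lower with it (2.86 for independent sets) and 12 the other way round (1.71). At a level of -2 or more on all arrays, 1 gene was higher in both (Postn), 4 were lower in both (Arg1, Cdkn2a, Mmp8 and Olr1) and 0 went opposite ways.

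The difference between the LPS responses of the genotypes was taken as CD163-deficient minus wild type. It was positive for Gsg1l (3.52), Dytn (3.45), Wbp2nl (3.10), of which Dytn and Wbp2nl were lower with LPS in wild type (-2.47 and -2.39) and higher in CD163-deficient cells (0.98 and 0.71), and for Spata24 (2.84), Plppr1 (2.68) and Heg1 (2.47). It was negative for Dgkg (-2.88), Clec5a (-2.86), Ces1e (-2.83), Hmx3 (-2.75), Zfp354b (-2.51) and Plscr4 (-2.48). Each of these had a level under -2 on at least 1 array. Dytn and Wbp2nl had their highest level on the wild-type array without LPS (-2.36 and -2.82). On the other arrays Dytn lay between -5.55 and -4.57 and Wbp2nl between -5.22 and -4.48, so their response differences rest largely on that 1 array. Among brighter genes, chosen after the values were seen, Serpina3g (1.31) and Plk3 (1.21) were positive, and Htatsf1 (-1.94) and Sptlc1 (-1.90) were negative. The value of Htatsf1 goes with its low level on the wild-type array without LPS (-0.08), against 0.91 to 1.47 on the other arrays. NF-kB feedback genes stood apart upward (median 0.26, 21 of 31 positive, percentile 98.92), and interferon-stimulated genes (0.19, percentile 77.75), class I genes (0.21, percentile 35.78, turning to -0.05 with quantile normalization) and the nitric oxide, prostaglandin and antimicrobial list (0.28, percentile 88.08) did not. All compared genes had a median of 0.08 here, so lists near 0 with members in both directions can lie low among random lists. Apart downward in that sense were the lists of matrix and protease genes (-0.03, 16 positive and 17 negative), complement and efferocytosis genes (-0.02, 13 and 16), the LXR, PPAR and lipid list (-0.04, 13 and 16), cholesterol synthesis (-0.10), cell cycle (-0.06) and alternative activation (-0.04, which turned to 0.08 with normexp). With quantile normalization the calls of cell cycle (percentile 5.75) and cholesterol synthesis (percentile 8.955) ended. In total 360 genes were at least 2-fold positive and 548 at least 2-fold negative of 23904, and at a level of -2 or more 25 and 130 were. The positive share was 39.7%, and it was 62.7% with normexp (250 and 149 genes).

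**Figure D3:**
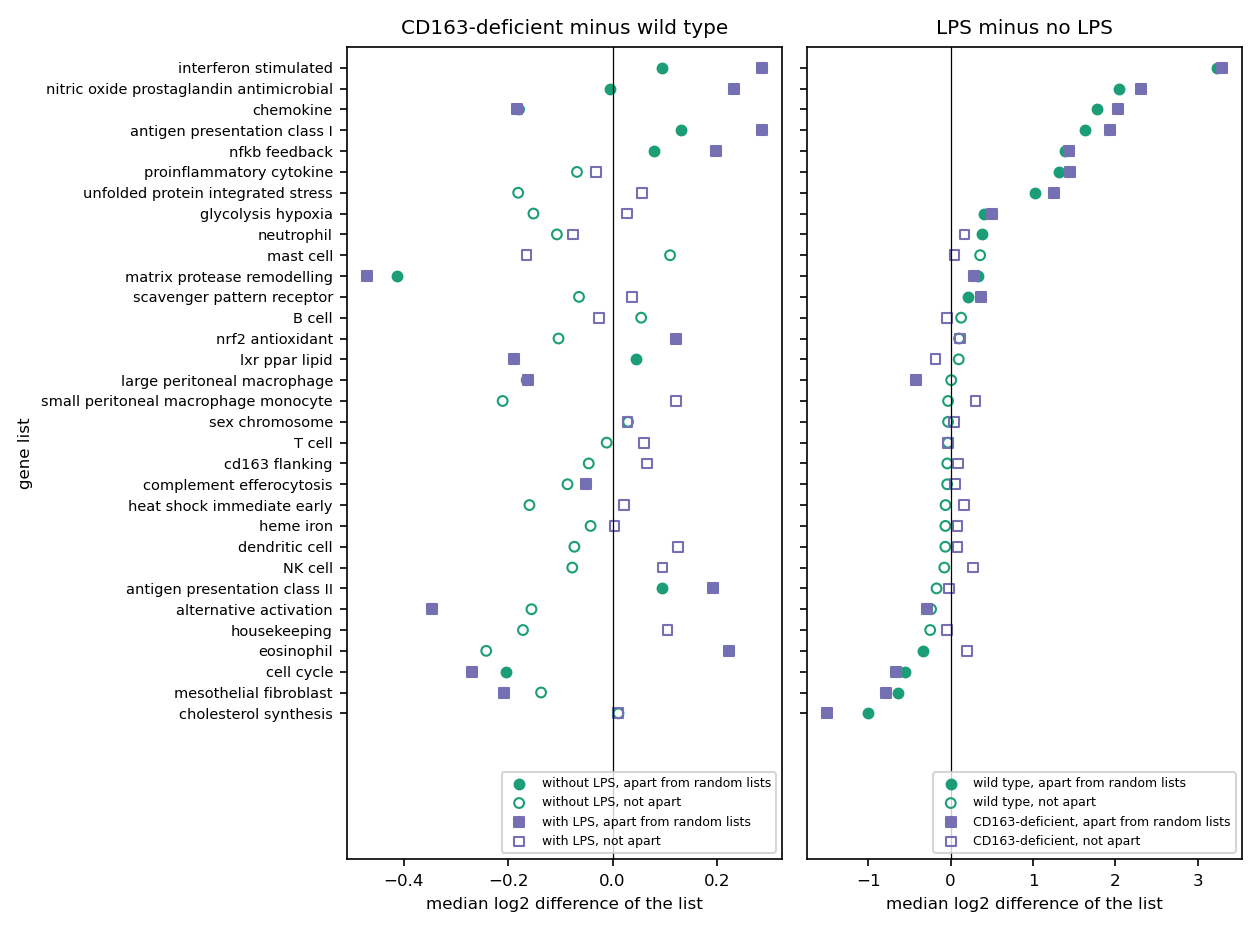
Median log2 difference of each of 32 gene lists, with the genotype comparisons on the left and the LPS comparisons on the right, and filled symbols for lists apart from matched random lists. With LPS the interferon-stimulated list was higher in CD163-deficient cells (0.29) and the matrix and protease list lower (-0.47), and cholesterol synthesis was the lowest list with LPS in both genotypes (-1.01 and -1.5).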

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

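Of the tests in this part, those of dim probes and of second probes were chosen only after the result was seen, and the test of RNA integrity was chosen before it. No difference in this part was tested against replicates, since each group holds 1 array, and what marked the list and the named genes of the next 2 paragraphs is that the direction was opposite under the same contrast in the other state or genotype.

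The list of LXR, PPAR and lipid genes was higher in CD163-deficient cells without LPS (0.04, percentile 99.49) and lower with LPS (-0.19, percentile 0), a gap of -0.23 between the medians. Gene by gene, the difference between the LPS responses had a median of just -0.04 (13 genes upward and 16 downward, percentile 0.22), and no replicate could test it. The value without LPS lost both its direction and its call with normexp (-0.017, percentile 96.24) and at a level of -2 or more (-0.0061, percentile 96.98).

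The genotype difference was at least 2-fold upward without LPS and at least 2-fold downward with LPS for 7 named genes, none of them tested. From the state without LPS to that with LPS it differed by -2.43 for Adad1, -2.29 for Adgrd1, -2.83 for Ces1e, -2.29 for Cyp2d9, -2.42 for Grk1, -2.75 for Hmx3 and -2.43 for Olfr56. The LPS difference itself had opposite directions in the genotypes, again untested, for Clec5a (1.45 in wild type and -1.41 in CD163-deficient cells, a gap of -2.86), Dgkg (1.04 and -1.84, a gap of -2.88), Dnajc28 (1.04 and -1.10, a gap of -2.14), Mest (1.03 and -1.14, a gap of -2.17) and Drd2 (-1.01 and 1.18, a gap of 2.20). Adad1, Ces1e, Cyp2d9, Grk1 and Hmx3 met both rules, with LPS differences higher in wild type and lower in CD163-deficient cells. Both gaps of a gene are the same quantity from the same 4 levels, so this is not a separate observation. Among genes well above background on all 4 arrays, and with transcripts that lack a gene name included, 14 showed opposite genotype differences and 16 opposite LPS differences, and 0 of them had a level of -2 or more on all arrays.

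Genes at least 2-fold apart between genotypes without LPS were mostly dim, and few of them were shared with the arrays with LPS. Poorer RNA in the wild-type culture without LPS was not seen as a large shift over all transcripts. Upstream and downstream probes of 2629 transcripts differed between the genotypes by a median of 0.042 (95% bootstrap interval 0.023 to 0.064), inside the bound of 0.1. The same array set against wild type with LPS gave 0.13 (0.101 to 0.152), beyond it. A median over all transcripts cannot speak for the 626 genes at least 2-fold apart, so RNA quality cannot be excluded for them. Noise of dim probes cannot be told apart from expression here. The level of -2, which 11.3% of these genes and 50.1% of those compared had, was chosen after most differences were seen to be dim. Simulated noise of spots called 212 of 25433 unchanged genes, against 626 of 25919 observed, without noise between cultures. That simulation took the median spread of spots at each level and so left out probes with a wider spread. A second detected probe was there for just 47 of these genes, and 11 of them (23.4%) showed the same direction at 1.5-fold or more on it. The exact interval was 12.3% to 38.0%, and the share for LPS in wild type was 61.5%. For most of these 47 genes this argues against an expression difference seen by every probe. Genes without a second detected probe were not covered, and for them expression cannot be told apart from noise. The genotype stays open as the cause of any of these differences and was not tested.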

How the results depend on the processing

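The setting that keeps genes at a level of -2 or more was chosen only after the data were seen, and all other settings were chosen before. No paired analysis was possible because each group holds 1 array and no replicate numbers pair them. For the same reason no replicate could be left out and no other splits of the samples exist. All 4 arrays share 1 slide, so no slide effect could be fitted. Between 81.0% and 87.3% of spots were well above background, and 3156 of 30156 genes were so on no array, which limits what can be said about dim genes. Normexp moved the median of all compared genes from -0.06 to -0.17 between genotypes without LPS and from 0.01 to -0.18 for LPS in wild type, so its values are read against those medians.

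Of the lists that stood apart, 4 of 8 kept their call under every setting chosen in advance for genotypes without LPS, 12 of 15 with LPS, 13 of 15 for LPS in each genotype, and 4 of 7 for the LPS response difference. The interferon-stimulated list stayed between 0.20 and 0.30 between genotypes with LPS, and the matrix and protease list between -0.55 and -0.43. Of 882 values of single named genes, 720 stayed within the tolerance with normexp, 862 with quantile normalization, 862 with the deposited table, 879 with scaling to the median and 798 with the mean of all probes.

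Counts of genes at least 2-fold apart moved by more than 1.5 times as follows. With normexp they were 48 higher and 106 lower between genotypes without LPS, and 96 and 34 with LPS. Normexp also gave 1053 higher for LPS in wild type, 865 lower for LPS in CD163-deficient cells and 149 negative for the response difference. It adds an offset of 50 to the intensities, which by construction shrinks the log2 differences of dim probes. At the main setting most genes 2-fold apart between genotypes were dim, with 11.3% without LPS and 4.02% with LPS at a level of -2 or more. How much of each change in count comes from the offset was not tested. Detection on both arrays gave 207 and 189, then 200 and 159, between genotypes without and with LPS, since genes detected on 1 array of a pair no longer enter. No detection filter gave 889 and 657, then 568 and 945, between genotypes, 2611 higher for LPS in wild type, and 1350 positive and 1823 negative for the response difference, since undetected genes enter and no bounds apply. A level of -2 or more gave 46 and 25, then 9 and 15, between genotypes. For LPS it gave 868 and 683 in wild type and 930 and 649 in CD163-deficient cells, and for the response difference 25 and 130. Fewer genes enter there, and between genotypes dim genes were also 2-fold apart more often. Without LPS 4.29% of dim and 0.547% of brighter genes were, and with LPS 4.235% and 0.183%. The correlation of LPS differences was 0.625 with no filter, and that of genotype differences was -0.0159 with normexp and -0.0369 with no filter, and the cause of the normexp value was not tested.

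Some list medians reversed, and the cause was not tested. With normexp, neutrophil markers for LPS in wild type were at -0.028, class II genes at -0.015 and the LXR, PPAR and lipid list at -0.017 between genotypes without LPS, and alternative activation genes at 0.080 for the response difference. The nitric oxide, prostaglandin and antimicrobial list (-0.01 between genotypes without LPS) was at 0.0052 with normexp, 0.042 with quantile normalization, 0.043 with the deposited table and 0.054 with the mean of all probes. That mean gave 0.082 for complement and efferocytosis genes between genotypes with LPS, 0.094 for markers of large peritoneal macrophages for LPS in CD163-deficient cells, and -0.31 for Zbtb46 in the response difference (1.11 on its brightest probe). With no filter, the large macrophage markers were at 0.0053 and the alternative activation genes of the response difference at 0.0021. At a level of -2 or more, these were at 0.46 and 0.18, the alternative activation genes for LPS in CD163-deficient cells at 0.066 and the LXR, PPAR and lipid list between genotypes without LPS at -0.0061.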

Other observations

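Of the tests in this part, those of scaling were chosen before the result was seen, and those of T and NK cell markers, of 1 larger LPS effect and of stromal markers were chosen only after it. Markers of large peritoneal macrophages took different directions with LPS in wild type. Prg4, which encodes the lubricant proteoglycan 4, was higher with LPS (4.69), as were Serpinb2 (3.45), Arg1 (3.27) and Cxcl13 (2.95), while the complement receptor gene Vsig4 was lower (-2.91). The list median was 0.01, and it turned to -0.04 with quantile normalization. In CD163-deficient cells the median was -0.42 (percentile 0.010), with Prg4 at 4.56 and Vsig4 at -3.00, and it turned upward with the mean of all probes (0.09). At a level of -2 or more the median was 0.46 and stood apart upward (percentile 99.56), so the direction of this list depends on the setting. Among neutrophil markers, Lcn2, Wfdc21 (4.79), Camp (3.90) and S100a8 (2.47) were higher with LPS in wild type (list median 0.38, percentile 98.95, 0.19 with undetected members at their bound, turning to -0.03 with normexp). Iron genes moved in both directions with LPS in wild type, with Cp, the ceruloplasmin gene, at 4.12, Spic at 2.47, Hp, the haptoglobin gene, at 2.32, Hmox1 at 1.62, Slc40a1 at -3.71 and Tfrc at -2.17.

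Beside the eosinophil markers (higher), the markers of large peritoneal macrophages (lower) and the mesothelial and fibroblast markers (lower), other cell type lists were not apart between genotypes with LPS. T cell markers had a median of 0.06, NK cell markers of 0.10, B cell markers of -0.03 (0.03 with normexp), mast cell markers of -0.16, dendritic cell markers of 0.12 (percentile 97.47), neutrophil markers of -0.08 (0.001 with normexp) and markers of small peritoneal macrophages and monocytes of 0.12 (0.05 with undetected members at their bound), and none of these 7 lists stood apart at the scaling used, although the mast cell median was as far from 0 as that of the large macrophage list. Over the 8 settings chosen in advance, dendritic cell markers were not apart in 5, and markers of small macrophages and monocytes in 6. The scavenger and pattern receptor list (0.04), the glycolysis and hypoxia list (0.03), the unfolded protein and integrated stress list (0.06), the heat shock and immediate early list (0.02) and cholesterol synthesis (0.01) did not stand apart either, and the signs of these 5 medians turned with quantile normalization. Control lists of housekeeping genes (0.11), of sex chromosome genes (0.03) and of genes that flank Cd163 (0.07) did not stand apart. The Y-linked Ddx3y (levels from 0.52 to 1.09) and Eif2s3y (0.81 to 1.25) were detected on all 4 arrays, Kdm5d and Usp9y were not detected on any, and Xist lay between -2.84 and -2.76.

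Interferon-stimulated, class I and NF-kB feedback genes were higher in CD163-deficient than in wild-type cells with LPS. Scaling between arrays is argued against, because the lowest median of the interferon-stimulated list over the scalings was 0.20, apart from random lists in each. A rise of T or NK cells as large as that of Ifng (1.14) is argued against as well, because 26 detected markers of those cells had an upper quartile of 0.18. NK cell markers alone had an upper quartile of 0.19 (8 of 12 higher), so a smaller rise of NK cells is not excluded. The abundant T cell marker Cd3e had a level of 0.32 in CD163-deficient cells against 0.44 in wild type. Thy1 (1.00 against 1.56) is also on the stromal list, so its lower level does not speak for T cell number. Whether 1 larger LPS effect on all responding genes was at work cannot be told apart from effects on some of them, because the 16 chemokine genes at least 2-fold higher with LPS in both genotypes had a median of -0.11 with quartiles from -0.51 to 0.14, while 453 genes at least 4-fold higher with LPS in wild type had a median of 0.24 and 193 genes at least 4-fold lower one of -0.17. Genotype stays open as a cause and was not tested.

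Matrix and protease genes were lower in CD163-deficient cells in both states. Scaling is argued against, because the highest median of that list over the scalings and both states was -0.26. Fewer stromal cells in the CD163-deficient cultures may account for part of the difference with LPS, where 6 abundant stromal markers (Sparc, Col1a1, Col1a2, Dcn, Col6a1 and Thy1, the last also a T cell marker) had a median of -0.58 against -0.47 for the list, with Sparc at 6.2 against 6.78 in wild type, although Postn was higher and all 24 mesothelial and fibroblast markers compared had a median of -0.21. The 6 markers were those with a level of 0 or more on both wild-type arrays. Picking markers by their wild-type level can favour lower values in CD163-deficient cells, so their median cannot decide this. Without LPS the markers had a median of -0.29, with quartiles from -0.51 to 0.06 around the -0.41 of the list, so there a stromal source cannot be told apart from a difference within macrophages, with 6 markers too few to decide. Genotype stays open in both states and was not tested.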
